A study of Caenorhabditis elegans with 15 samples.

How the data were processed

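The series holds 15 polyA RNA-seq libraries made from whole *Caenorhabditis elegans* animals at the L4 larval stage. Per the labels, 6 libraries came from wild-type N2 animals and 3 each from animals given as mec-8 (e398) KO, u74 KO and u218 KO, here called e398, u74 and u218. The deposited table gives a signal for each of 46926 genes and 4 genotypes, in averaged normalized counts. The table's name calls its values averaged normalized counts; division of read counts by library size factors, and averaging over the libraries of each genotype, were read from the name and from the repeated steps of the values. Their notes name bedtools, HTSeq, DESeq and DESeq2 without versions, and the aligner, genome build, annotation and library strandedness are not given in the sources used here. Because strandedness was not stated, reads of genes that overlap on opposite strands cannot be separated, and members of gene families with near-identical sequence share reads to an unknown extent. All 46926 gene identifiers matched the WBcel235 annotation, release 115, which gave symbols and positions. Values were keyed by identifier, since 628 symbols stood on more than 1 identifier; gene lists were matched by symbol, apart from 1 member given by its identifier.

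Each comparison used log2((average + 1)/(average + 1)) of 2 genotypes among genes with an average of at least 20 normalized counts in either, and counted a gene as higher or lower at 2-fold or more. These averages carry no replicate error, so they were not tested. The comparisons, the named genes and 39 gene lists were fixed before the data were examined. The rule took mec-8, the 4 described MEC-8 splicing targets, and for each mutant against wild type the 12 highest and 12 lowest ratios among genes at 50 normalized counts or more. It added the 15 highest and 15 lowest genes of the set that moved one way in all mutants, the 6 highest and 6 lowest for each pair of mutants, and the most abundant members of each list discussed. The text names a part of these genes, and genes named outside that rule are marked as such. Of the lists, 38 had measured members. The median ratio of each list was placed among 10000 random lists of equal size drawn from 20 bins of expression; the percentile is a description and not a test. The 3 comparisons with wild type share 1 control column, so overlaps and correlations are printed with the values for independent lists and for 100 simulated data sets in which no gene changed. These simulations drew normal errors on the log2 scale. The wild-type spread was taken from the mutant libraries, and no library stood apart and no wild-type sets were unlike. Their values therefore need not hold for unchanged genes in the real data.

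Whole reads per library were then recovered, a step chosen after the data were seen. The smallest values of a column fall on repeated steps, each the weight of 1 read in 1 library, and the steps give the library size factors. There were 3 steps in each mutant column and 6 in the wild-type column, as many as the labelled libraries. In the mutant columns, 100% of nonzero values below 300 normalized counts had exactly 1 whole-read solution (15728, 13415 and 14353 values in e398, u74 and u218). Among wild-type values below 8, 99.9% of 9926 did. Values moved off their place had a solution in 0.222% of wild-type, 0.216% of e398, 4.82% of u74 and 2.65% of u218 cases. On simulated data the drawn reads were returned for 99.0% of wild-type values, 100% of e398, 99.9% of u74 and 100% of u218 values. The recovered libraries carry no replicate numbers and are numbered here by falling size factor.

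Genes with all libraries of 2 groups resolved and a mean of at least 5 normalized counts were tested with limma (trend) on log2(normalized count + 1), with Benjamini-Hochberg adjusted p under 0.05. Against wild type only genes with a wild-type average under 8 could enter this test, so rises could be called there and falls hardly, and this choice of genes favours rises even without a change. The p-values rest on a spread between samples that limma shares between genes, and this spread may be technical. They do not show how well the libraries of a single gene agree. In e398 against wild type, D1086.9 passed (limma adjusted p = 8.12e-05) with e398 libraries from 2.92 to 361 normalized counts. Tested on simulated data with 200 genes changed 4-fold, limma recovered 67.0%, 83.5% and 79.0% of them for e398, u74 and u218 against wild type, and 74.0%, 71.0% and 87.0% for u74 against e398, u218 against e398 and u218 against u74. In the order of those 6 comparisons, 6.94%, 1.76%, 0.629%, 1.99%, 4.70% and 3.33% of calls were unchanged genes. These simulated counts had 1 spread for all genes and libraries, no library apart and no sets of unlike wild-type libraries. In the real data, u218 library 3 differed at least 4-fold from both others for 31.8% of genes, so these rates need not hold there.

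Alternatives fixed beforehand were pseudocounts of 0.5 and 10, no filter or a minimum of 100 normalized counts, ratios recentred on their median, TMM factors computed from the columns, and thresholds of 1.5-fold and 4-fold. Those added for limma after the data were seen were voom, pseudocounts of 0.5 and 5, minimum means of 2 and, for pairs of mutants, 15, each library left out in turn, and wild-type libraries of like size factor alone. The latter were the 3 of small size factor for e398 and the 3 of large size factor for u74 and u218. The size factor of u218 library 3 (0.831) lay between both sets. TMM factors moved all ratios to wild type by -0.06 in e398, 0.18 in u74 and 0.31 in u218 on the log2 scale. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. Total reads per library are not in the deposit, so no counting interval was computed for the averages. In the wild-type average 1 read weighed 0.0915 to 0.354 normalized counts, in e398 0.487 to 0.701, in u74 0.171 to 0.229 and in u218 0.168 to 0.401.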

Results

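Transcript levels were measured in whole L4-stage animals of 4 genotypes with 15 polyA RNA-seq libraries: 6 wild-type (N2), 3 labelled mec-8 (e398) KO, 3 labelled u74 KO and 3 labelled u218 KO. MEC-8 is an RNA-binding protein with RNA recognition motifs that regulates alternative splicing; the deposited values are sums per gene and do not separate splice forms. The table gives 1 averaged normalized count per genotype and gene, and 16101 of 46926 genes were at 0 in all columns. Column totals were 97187743 normalized counts in wild type, 126747904 in e398, 63068771 in u74 and 68830842 in u218. The 10 most abundant genes took 12.2%, 14.9%, 6.13% and 5.95% of these totals, and ribosomal RNA took 1.87%, 2.22%, 0.809% and 0.536%. Size factors recovered from the values ran from 0.471 to 1.82 in wild type, 0.476 to 0.685 in e398, 1.46 to 1.95 in u74 and 0.831 to 1.99 in u218. Averages have no replicate error and are described as higher or lower; rose and fell are used only for genes that passed limma on the recovered reads, whose values are means ± SD over libraries.

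mec-8 (WBGene00003172; chromosome I, 9441010 to 9444227, minus strand, WBcel235) averaged 1956 normalized counts in wild type, 1069.7 in e398, 2239 in u74 and 3619.8 in u218. Its log2 ratios to wild type were -0.87, 0.19 and 0.89, none of which reached 2-fold; after recentring and with TMM factors the u218 ratio of mec-8 was 1.15 and 1.198, past 2-fold. Transcripts of mec-8 were thus present in all 3 groups labelled KO. A lesion need not remove its gene's transcript, and the kind of lesion is not given in the labels. This level therefore did not check the labels. The name of the deposited data speaks of MEC8 mutants, but the u74 and u218 labels give no gene. The groups are named as their libraries were labelled. Its reads per library were beyond the range that could be recovered, and the ratios were not tested.

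Among the 4 described splicing targets of MEC-8, the perlecan gene unc-52, whose span overlaps hhat-1, averaged 109901 in wild type, 145342 in e398, 57984 in u74 and 62714 in u218. The stomatin-like touch-channel gene mec-2 averaged 2136, 3036, 606 and 1123 in the same order. The fibrillin-related gene fbn-1 had log2 ratios of -0.40 in e398, -3.73 in u74 and -1.20 in u218; the u218 value was -0.93 after recentring and -0.89 with TMM factors, short of 2-fold. The kinase gene sad-1 had ratios of 0.41, -1.11 and -0.19, and the u74 value was -0.93 with TMM factors. As a list, the 4 genes had a median ratio of 0.40 in e398 (percentile 76.2 among random lists), -1.46 in u74 (5.39) and -0.87 in u218 (13.8).

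The first comparison asked which transcripts differ between mec-8(e398) and wild type. In e398, transcripts of ribosomal proteins and oocytes were lower, while those of histones, cilia and major sperm proteins were higher. Of 78 cytosolic ribosomal protein genes, 73 were at least 2-fold lower and 1 higher, with a median log2 ratio of -2.01; rpl-4 averaged 157237 in wild type and 70962 in e398. Of 23 oocyte genes 20 were lower and 0 higher (median -2.66), among them the eggshell proteoglycan genes cpg-1 (14628 and 2557) and cpg-2 (ratio -3.16). The germline translational repressor gld-1 averaged 19735 and 2029.8, among the 14 lower genes of 37 for germline proliferation and meiosis (0 higher, median -0.80). Of 58 histone genes 43 were higher and 4 lower (median 1.39), while the ribosomal RNA share was 1.87% in wild type and 2.22% in e398. Of 31 major sperm protein genes 19 were higher and 9 lower (median 1.38), with msp-59 at 11256 and 52606. The e398 libraries were uneven for the sperm genes that could be resolved, as given below. Of 48 ciliated sensory neuron genes 24 were higher and 1 lower (median 0.99), among them the intraflagellar transport gene osm-5 (1930.2 and 8653). Of 48 neuropeptide genes 21 were lower and 0 higher (median -0.62), and of 31 RNA splicing regulators 11 were lower and 0 higher (median -0.66), with the SR protein gene rsp-3 at -1.05.

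The highest single ratios in e398 included several genes on chromosome V. The neighbours spig-5 (52.9 in wild type, 10222 in e398), spig-4 (138 and 10369.6) and F14D7.14 (6.80 and 707) had ratios of 7.57, 6.22 and 6.50, and F11A5.17, F57E7.4 and F57E7.2 had ratios of 5.92, 5.43 and 5.20; F48C1.9 on chromosome I had 5.57. The cuticle collagen gene col-120 averaged 13111 and 446396 (5.09). At the other end, ZK813.1, ZK813.2, C17E7.4 and F54D10.7 averaged 621, 177, 153 and 135 in wild type and were listed at 0 in e398. K04C1.5 (ratio -7.32), T06D4.1 (-7.08) and the double-stranded noncoding RNA gene rncs-1 (-7.11; 623 and 3.53) were also low, as were the secreted-protein gene scl-7 (130.0 and 0) and the C-type lectin gene clec-92 (174 and 0.487).

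In total, 1987 genes were at least 2-fold higher and 3466 lower in e398, of 17398 considered. The recovered reads of 1228 genes with a low wild-type average, a choice that favours rises, could be tested with limma, and 35 rose and 0 fell at Benjamini-Hochberg adjusted p under 0.05 (207 at unadjusted p under 0.05; 409 rose and 0 fell by limma voom). The pore-toxin sensitivity gene hpo-25 rose most clearly, to 247 ± 35.1 (SD, n = 3) from 7.81 ± 8.68 (n = 6), a limma log2 ratio of 5.68 ± 0.79 (SE) with adjusted p = 8.77e-10. The tetraspanin genes tsp-4 and tsp-5, the cathepsin B-like gene cpr-2, and C55A1.7, D1086.9, F49C12.1 and T05B4.8 also rose (limma adjusted p from 1.90e-05 to 0.00999). D1086.9 and F49C12.1 were uneven, from 2.92 to 361 and from 1.64 to 242 among e398 libraries, and the lowest library of each lay below the wild-type mean, 3.36 for D1086.9 and 2.34 for F49C12.1. By limma, 2 of 161 testable chemoreceptor genes rose (0 adjusted over the list alone) and 1 of 9 C-type lectins (2 adjusted over the list alone). Against the 3 wild-type libraries of small size factor alone, 25 of 1772 genes rose by limma. The count of 35 became 15 or 13 without e398 library 1 or 3, and 22, 21 or 79 without wild-type library 1, 2 or 6. Recovered e398 library 2 differed at least 4-fold from both others for 213 genes upward and 487 downward of 5571, and its median over 8 resolved sperm genes was 20.5, against 153 and 201 in the others.

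**Figure D1:**
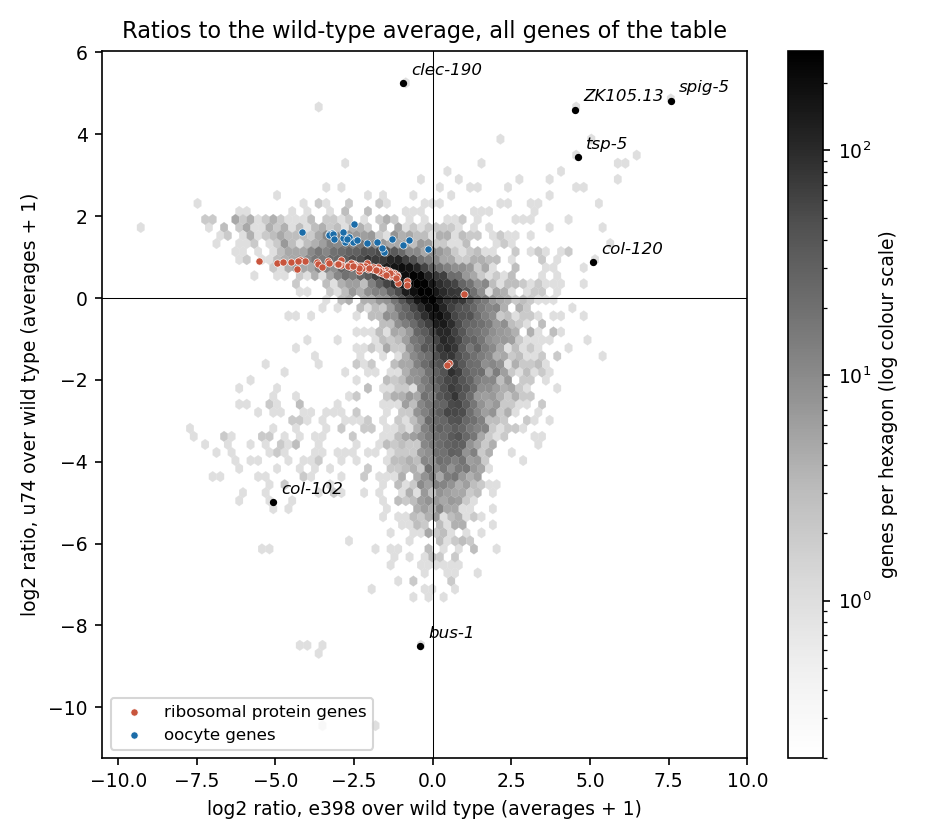
Log2 ratio of averages in e398 (horizontal) against that in u74 (vertical), both over the wild-type average; shading gives genes per hexagon on a log scale, and coloured points are ribosomal protein and oocyte genes. Most genes lie on a bent band through the upper left and lower right, with a correlation across genes of -0.40 among 17771 genes; spig-5, ZK105.13 and tsp-5 lie above 0 on both axes.

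The comparison of u74 with wild type gave a different set. In the u74-labelled libraries, oocyte and yolk transcripts were higher, and transcripts of detoxification enzymes, touch and ciliated neurons and moulting were lower. All 23 oocyte genes were at least 2-fold higher (median log2 ratio 1.45), with cpg-1 at 14628 in wild type and 51282 in u74 and the eggshell gene cbd-1 at 1.45. Of 10 adult-onset and yolk genes 7 were higher and 2 lower (median 1.25), including the vitellogenin genes vit-2 (152403 and 405211) and vit-6 (1.30). Ribosomal protein genes had a median of 0.73, with 0 of 78 higher at 2-fold and 2 lower, rpl-7A (-1.60) and rpl-12 (-1.65). Of 66 UDP-glucuronosyltransferase genes 55 were lower and 1 higher (median -2.89), and of 69 cytochrome P450 genes 54 were lower and 4 higher (median -2.39), with ugt-26 at 32768 and 3234 and cyp-35C1 at -4.48. Of 164 C-type lectins 8 were higher and most were lower (median -2.23), for instance clec-50 (-3.64).

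Touch neuron, ciliated neuron and moulting genes were also lower in u74, whereas 48 neuropeptide genes had a median of 0.38 (2 higher and 14 lower; percentile 99.2). Of 19 touch receptor neuron genes 13 were lower and 0 higher (median -1.51), among them the tubulin genes mec-7 (15100.5 in wild type, 1581 in u74) and mec-12 (-3.47) and the tubulin acetyltransferase gene mec-17 (-3.47), whose span overlaps arf-5. Of 48 ciliated sensory neuron genes 31 were lower and 0 higher (median -1.40), with osm-5 at -3.26, and of 53 histone genes 44 were lower and 1 higher (median -1.79), while the ribosomal RNA share was 1.87% in wild type and 0.809% in u74. Of 39 moulting and apical matrix genes 26 were lower and 0 higher (median -1.39), including the hedgehog-related gene wrt-1 (-5.13) and the lipocalin gene lpr-3 (-4.78). Chemoreceptor genes were lower in 136 cases and higher in 8 (median -2.57), although random lists of like expression had a median of -1.88. Among the lowest ratios were those of D1014.6 (9267 and 5.63), Y48E1B.8 (90629 and 66.9), BE0003N10.6 (-8.62) and bus-1, an acyltransferase gene needed for surface binding of a bacterial pathogen (33786 and 91.6). The collagen genes col-36 (354 and 0; its span overlaps dyf-13) and col-176 (663482 and 4385) and the abundant gene D1086.3 (-7.14) followed. Among the highest were the C-type lectin gene clec-190 (5.26), the collagen gene col-95 (67.5 and 1773), ZK105.13 (20.4 and 521), spig-5 (4.82) and the neighbours C36C5.15 (3.81) and C36C5.14 (3.22).

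In total 1101 genes were at least 2-fold higher and 4930 lower in u74, of 17004 considered. TMM factors raised the share of higher genes from 18.3% to 30.6%, and left 1980 higher and 4499 lower. By limma, 23 of 591 testable genes rose and 0 fell at adjusted p under 0.05 (85 at unadjusted p under 0.05; 19 rose and 0 fell by voom). The C-type lectin genes clec-190 and clec-222 rose to 72.5 ± 62.1 and 61.0 ± 51.1 (SD, n = 3) from 0.923 ± 1.76 and 5.36 ± 10.7 (n = 6), both with limma adjusted p = 2.29e-05; they were 2 of 6 testable lectins (2 adjusted over the list alone). Against the 3 wild-type libraries of large size factor, 6 of 504 genes rose by limma; clec-190 did (adjusted p = 0.0301) and clec-222 did not (adjusted p = 0.35). Each u74 library left out in turn lowered the count to between 4 and 7, and it was 13 without wild-type library 5.

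The comparison of u218 with wild type gave shifts in reproductive and adult transcripts, among others. In the u218-labelled libraries, sperm, oocyte, yolk and adult cuticle genes were lower, and ribosomal protein and neuropeptide genes were higher. Of 59 sperm genes 58 were at least 2-fold lower and 0 higher (median log2 ratio -5.31), and all 31 major sperm protein genes were lower (median -6.08), with msp-59 at 11256 in wild type and 70.1 in u218. Of 23 oocyte genes 21 were lower and 0 higher (median -2.47), including the yolk receptor gene rme-2 (11919 and 1199.8). Of 10 adult-onset and yolk genes 8 were lower and 0 higher (median -6.90): vit-2 averaged 152403 and 1046, and the adult collagen gene col-19 averaged 26368 and 143. Ribosomal protein genes were higher in 69 of 78 cases and lower in 3 (median 1.31), with rpl-4 at 157237 and 351423. Of 48 neuropeptide genes 25 were higher and 6 lower (median 1.06), and of 31 splicing regulators 1 was higher and 4 were lower (median 0.36). Among 49 sperm genes whose reads were recovered in u218, the medians of libraries 1, 2 and 3 were 8.05, 11.1 and 147 normalized counts. Library 3 differed at least 4-fold from both others for 31.8% of 4961 genes.

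Detoxification and lectin genes were lower in u218 as in u74, and so were many collagen genes. Of 44 cuticle collagen and furrow genes, 28 were lower and 7 higher in u218 (median -1.37), and 23 lower and 6 higher in u74 (median -1.24). These counts of averages were not tested against each other. Of 136 genes named col, 98 were lower and 8 higher (median -2.22), against 64 lower and 25 higher of 135 in u74 (median -0.78), with col-120 at 13111 in wild type and 146 in u218, while the larval furrow collagen gene dpy-7 was higher (4904 and 19986). Of 66 UDP-glucuronosyltransferase genes 52 were lower and 0 higher (median -2.31), of 69 P450 genes 52 lower and 3 higher (median -2.15), and of 163 C-type lectins 12 higher and most lower (median -1.72). The highest ratios included the metallothionein gene mtl-1 (54.6 and 1668; 4.91), the lipase-related gene lips-6 (449 and 12559.8), the secreted-protein gene scl-24 (4.77), the infection-response gene irg-5 (389 and 7549; 4.27) and T19C3.3, T26H5.9 and C08E3.13 (4.63, 4.51 and 4.35). Among the lowest were K06H6.1 (5469 and 0.401), K06H6.2 (-9.87), C14C6.8 (-9.86), C14C6.6 (776 and 0), Y71G12B.18 (-9.52), F55B11.2 (2134 and 5.82), the sperm-specific gene ssp-19 (-8.20) and the uterine-lumen gene ule-3 (4172 and 14.0).

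In total 1784 genes were at least 2-fold higher and 6122 lower in u218, of 17087 considered. The share of higher genes, 22.6%, became 37.1% with TMM factors (3172 higher, 5377 lower) and 34.96% after recentring (2948 higher, 5484 lower), since the median of all ratios was -0.26. By limma, 28 of 674 testable genes rose and 0 fell (128 at unadjusted p under 0.05; 56 rose and 0 fell by voom). C08E3.1 rose to 205 ± 135 (SD, n = 3) from 3.92 ± 4.20 (n = 6), a limma log2 ratio of 5.63 ± 0.72 (SE) with adjusted p = 3.39e-12, and cpr-2 rose to 159.5 ± 174 from 5.84 ± 7.78 (limma adjusted p = 1.67e-07). Against the 3 wild-type libraries of large size factor, 19 genes rose and 3 fell of 589 by limma, C08E3.1 (adjusted p = 0.00366) and cpr-2 (adjusted p = 0.0105) among those that rose. The count of 28 became 14 or 10 without u218 library 1 or 2.

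**Figure D2:**
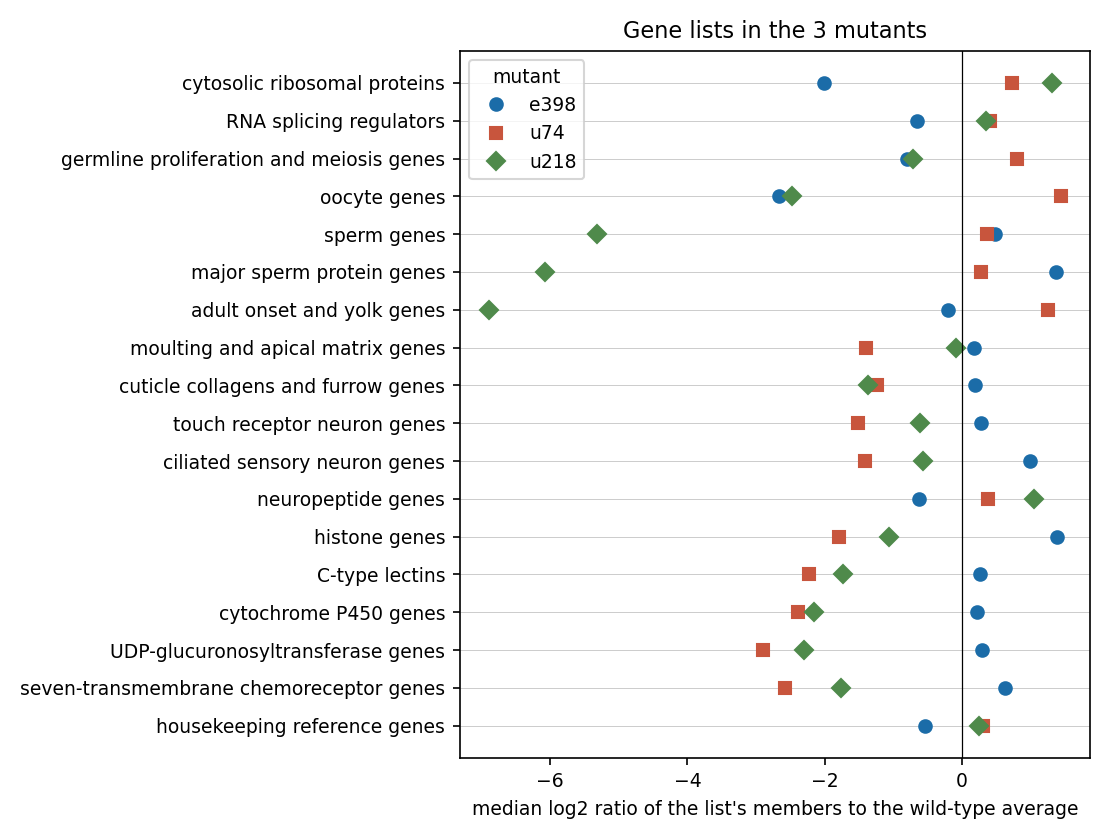
Median log2 ratio of the measured members of 18 gene lists fixed beforehand to the wild-type average (horizontal), with 1 point per mutant and no error because averages were compared. Major sperm protein genes sit at 1.38 in e398, 0.27 in u74 and -6.08 in u218.

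Few genes moved the same way in all 3 mutants: 28 were at least 2-fold higher and 233 lower, of 16782 considered in every comparison. Independent lists of these sizes would share 8.89 higher and 371 lower genes, and simulated data without change, which carry the shared wild-type column, gave 48.5 and 47.9. At 4-fold 12 were higher and 131 lower, against 0.00454 and 54.3 for independent lists and 0.03 and 0.05 in the simulations. The simulations had normal errors and no unlike wild-type libraries, so they do not show how many genes would be shared without change. The higher genes lay mostly on chromosome V, 19 of 28 where the share of the 17771 genes at 20 or more normalized counts would give 6.03. Some are neighbours and so not independent placements. Of the higher genes 0 lay within 2 Mb of mec-8, where 1.34 would be given. They included ZK105.13 (20.4 in wild type, then 492, 521 and 1006), the spig-4, spig-5 and F14D7.14 neighbours, spig-6, lips-6, scl-24, the C-type lectin gene clec-174 (9.53, then 58.0, 69.0 and 59.2) and the neighbours T05B4.8 and T05B4.9. In 7 of the 28 genes all mutant averages were above 6 times the wild-type average, and so above the value of any single wild-type library.

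The tetraspanin genes tsp-4 (chromosome IV, 12519119 to 12520250) and tsp-5 (chromosome IV, 13590607 to 13591745) rose in all 3 mutants by limma. Wild-type libraries averaged 6.02 ± 7.08 for tsp-4 and 1.84 ± 1.53 for tsp-5 (SD, n = 6). Expression of tsp-5 was 68.5 ± 19.6 in e398, 29.7 ± 3.29 in u74 and 33.7 ± 7.67 in u218 (SD, n = 3), with limma adjusted p of 8.12e-05, 0.00277 and 0.00166. For tsp-4 the means were 111 ± 55.2, 60.3 ± 23.6 and 66.4 ± 18.8, with limma adjusted p of 1.90e-05, 2.29e-05 and 2.47e-05. Every mutant library exceeded every wild-type library for both genes. With the wild-type libraries of like size factor alone, limma adjusted p was 5.13e-05, 0.0301 and 0.00999 for tsp-5 and 0.00013, 0.045 and 0.0108 for tsp-4. In u218 the likeness holds for libraries 1 and 2 alone, since library 3 had a size factor of 0.831. T05B4.8 rose too (limma adjusted p = 0.000889, 0.00333 and 0.00332), but with wild-type libraries of like size factor adjusted p was 0.000925 in e398, 0.127 in u74 and 0.0737 in u218.

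**Figure D3:**
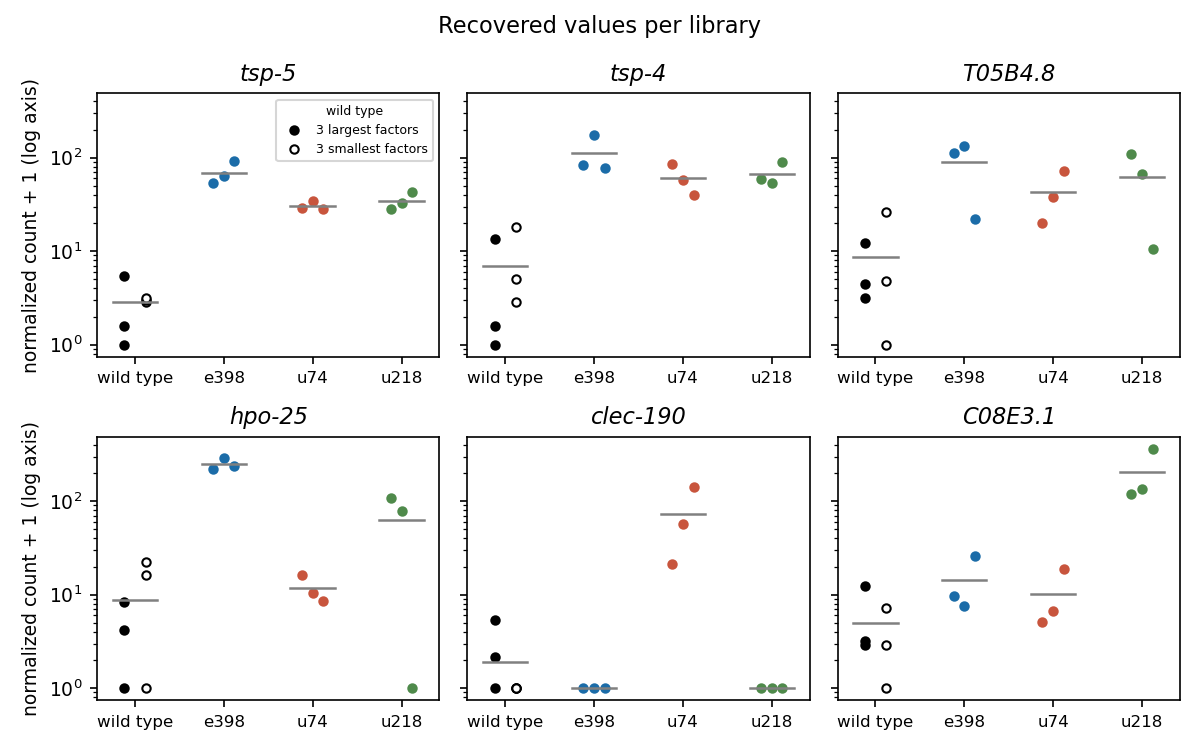
Normalized counts + 1 per recovered library (log axis) for 6 genes, with wild-type libraries of the 3 largest size factors filled and of the 3 smallest open; grey lines are group means. For tsp-5 the wild-type libraries lie between 0 and 4.41 normalized counts and the mutant libraries between 27.2 and 90.4.

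Among the 233 lower genes were the collagen genes col-102 (69.7 in wild type, 1.24 in u74 and 0 in u218) and col-36, the cuticlin gene cut-3 (577, then 12.4, 7.76 and 33.3; its span overlaps evl-20), the C-type lectin gene clec-207 (289.7 in wild type, 6.49 in e398 and 9.94 in u74), the astacin protease gene nas-17 (0 in e398, 2.62 in u74 and 0 in u218), scl-7 and F43C11.2. For 54 of the 220 such genes with a wild-type average under 2000, the wild-type value resolved to reads of wild-type library 3 and at most 10 reads in the other 5. Of the genes named by the rule these were C16C8.19, C33G3.5 and K11D12.6. With these 54 genes set aside, 207 of the 261 genes that moved the same way in all mutants remained. This count follows from the choice of the 54 genes, and the other genes were not recomputed without that library.

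The ratios to the shared wild type ran in opposite directions in e398 and u74. Across 17771 genes, which are not independent replicates, the correlation of ratios was -0.40 for e398 and u74 (covariance -0.78), where unchanged simulated data with the shared control gave 0.47 (0.15). For e398 and u218 it was -0.19 (covariance -0.44; simulated 0.24 and 0.15), and for u74 and u218 0.42 (1.18; simulated 0.36 and 0.15). The simulated values rest on normal errors without unlike wild-type libraries. In e398 and u74, 61 genes were higher and 254 lower in both, against 95.8 and 1017 for independent lists, and 907 and 815 were called in opposite directions, against 476 and 204. In e398 and u218 these counts were 86, 689, 1089 and 775 (independent 156, 1261, 597 and 330.3). In u74 and u218 they were 143, 3535, 366 and 41 (independent 98.3, 1789.7, 368 and 477).

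The direct comparison of u74 with e398 did not use wild type, but library set and genotype cannot be told apart in it. Size factors of e398 (0.476 to 0.685) lay near the small wild-type set (0.471 to 0.531). Those of u74 (1.46 to 1.95) lay near the large set (1.59 to 1.82). These wild-type sets differed by limma in 416 of 986 testable genes, though in 0 without wild-type library 1. Against e398, the u74-labelled libraries had higher oocyte, ribosomal and germline transcripts and lower histone, cilium, detoxification and collagen transcripts. All 23 oocyte genes were higher (median log2 ratio 4.16), as were 75 of 78 ribosomal protein genes (2 lower, median 2.74) and 25 of 37 germline proliferation and meiosis genes (2 lower, median 1.63). Of 67 UDP-glucuronosyltransferase genes 59 were lower and 0 higher (median -3.23), and of 48 ciliated neuron genes 40 were lower and 2 higher (median -2.46). The highest ratios included those of ZK813.1 (0 in e398, 1886 in u74), ZK813.2 (0 and 830), C17E7.4 (0 and 587), K04C1.5 (9.17), rncs-1 (3.53 and 2345) and T06D4.1 (8.91), and the lowest included Y48E1B.8 (-8.46), K06H6.1 (-8.21), bus-1 (25350.1 and 91.6), sysm-1 (-8.05), D1086.3 (-7.91) and col-176 (-7.69). Of 17376 genes 4839 were higher and 6456 lower at 2-fold. By limma, 962 rose and 2380 fell of 6590 testable genes. Chemoreceptor genes made up 424 of these, of which 9 rose and 248 fell (12 and 255 adjusted over the list alone), and of 27 histone genes 23 fell (24 adjusted over the list alone), while the ribosomal RNA share was 2.22% in e398 and 0.809% in u74. The median ratio of chemoreceptor averages was -3.04, against -2.05 for random lists of like expression (percentile 0), so much of this shift was shared by genes of that level. All 10 testable UDP-glucuronosyltransferase genes but 1 fell (9 adjusted over the list alone), and 5 of 9 neuropeptide genes rose (5 adjusted over the list alone). hpo-25 fell from 247 ± 35.1 to 10.8 ± 4.09 (SD, n = 3 each; limma log2 ratio -4.44 ± 0.41, adjusted p = 0.000543).

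Between u218 and e398, averages of major sperm protein and yolk genes were lower in u218, while oocyte genes had no common direction. Against e398, all 31 major sperm protein genes were lower in u218 (median log2 ratio -7.53), as were 8 of 10 adult-onset and yolk genes (median -5.67), while oocyte genes divided into 3 higher and 5 lower of 23 (median 0.04). The u218 libraries were uneven here. Among 29 resolved major sperm protein genes, u218 library 3 had a median of 158, against 9.56 and 15.0 in libraries 1 and 2. Ribosomal protein genes were higher in 75 of 78 cases (median 3.27) and neuropeptide genes in 26 of 48 (8 lower, median 1.75). High ratios included those of rncs-1 (3.53 in e398, 3342 in u218), C35E7.6 (7.81), H20J04.6 (7.66) and Y94H6A.7 (7.30), and the lowest included K06H6.1 (15207 and 0.401), col-120 (446396 and 146), K06H6.2 (-11.45), F26F2.10 (-11.08) and the astacin protease gene nas-22 (-10.72). Of 17255 genes 4640 were higher and 7022 lower at 2-fold. Size factors ran from 0.476 to 0.685 in e398 and from 0.831 to 1.99 in u218, so here too they cannot be told apart from genotype. By limma 727 rose and 2002 fell of 6567, and the count of 2729 became 1417 or 1285 without u218 library 1 or 2 and 1557 or 1725 without e398 library 1 or 3. The calls included 163 falls and 11 rises among 479 chemoreceptor genes (143 and 8 adjusted over the list alone) and 13 falls among 28 histone genes (19 adjusted over the list alone), while the ribosomal RNA share was 2.22% in e398 and 0.536% in u218. Chemoreceptor averages had a median ratio of -2.40, against -2.07 for random lists of like expression (percentile 5.97). Their falls stand beside 2002 of 6567 over all tested genes. C55A1.7 fell from 80.7 ± 31.7 to an average of 3.80 (n = 3 each; limma adjusted p = 0.00518).

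Between u218 and u74, genes of the germline and adult were lower in u218 and those of touch neurons and moulting were higher. Of 59 sperm genes 58 were lower (median log2 ratio -5.83), of 23 oocyte genes 22 (median -4.05), and of 37 germline proliferation and meiosis genes 26 (0 higher, median -1.21), with gld-1 at 47517 in u74 and 6632 in u218. Of 10 adult-onset and yolk genes 8 were lower (median -7.91). Of 39 moulting and apical matrix genes 26 were higher and 1 lower (median 1.59), with the moulting gene mlt-11 at 10792 and 55947, and of 19 touch receptor neuron genes 15 were higher and 1 lower (median 1.33). Of 53 pathogen and epidermal defence genes 26 were higher and 5 lower (median 0.99); by limma 3 of 19 testable ones rose (3 adjusted over the list alone). Other high ratios included those of Y17D7C.2 (6.32), the collagen gene col-41 (1599 and 100325), the acyltransferase gene oac-29 (5.93) and the alpha-tubulin gene tba-8 (5.66), and the lowest included ZK813.1 (-10.22), ule-3 (12583 and 14.0), Y62H9A.4 (-9.58) and F55B11.2 (-9.55). Of 16279 genes 3045 were higher and 3356 lower at 2-fold; TMM factors turned this balance (3707 and 3113) and recentring widened it (2328 and 3725). By limma 657 rose and 979 fell of 6120, and without u218 library 3 1962 rose and 1441 fell. Without any other of the 6 libraries the limma count of 1636 became 753, 687, 767, 512 or 601, with rises down to 101. Y17D7C.2 rose from 2.40 ± 2.01 to 270.4 ± 138 (SD, n = 3 each; limma log2 ratio 6.37 ± 0.61, adjusted p = 0.00132), and 9 of 34 ciliated neuron genes rose and 0 fell (10 adjusted over the list alone).

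Within wild type, the 6 recovered libraries fell into 3 with size factors of 1.59 to 1.82 and 3 with 0.471 to 0.531. These are samples grouped from the data and not groups of the study. By limma, 350 genes were higher and 66 lower in the libraries of small size factor, of 986 testable genes (513 at unadjusted p under 0.05; 356 and 9 by voom). Without wild-type library 1 limma called 0 (418 at unadjusted p under 0.05), and without library 2 it called 162. The wild-type average lay between e398 and the mean of u74 and u218 for 80.04% of 17771 genes; with u74 or u218 set against the mean of the other mutants the shares were 56.5% and 55.7%.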

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

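All tests in this part were chosen only after the result was seen. A single library stood apart from the other 5 wild-type libraries for 5 of 13 genes whose reads were recovered in all 6, where chance flags about 1 in 20 for normally distributed values. That rate does not hold for these genes, which have few reads and many values of 0, so their number is not read against it. The measure is the gap of the extreme library to its neighbour over the whole range, and each value lay above the 95% critical value of Dixon's test for 6 samples. It was 0.740 for clec-190 (library 1 at 4.39 normalized counts, the next at 1.14) and 0.851 for clec-222 (library 1 at 26.9, the next at 4.00). It was 0.635 for cpr-2 (library 4 at 20.7, the next at 7.56) and 0.819 for the male-neuron gene cwp-3 (library 3 at 20.8, the next at 3.77). For C55A1.7 it was 1, but this is a single read in library 5 (2.04 normalized counts) with the others at 0, which fixes the ratio.

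Ratios to wild type ran opposite ways in e398 and in u74 for 1722 genes. With TMM factors 2228 genes were called opposite ways. These factors moved the ratios by only -0.06 in e398 and 0.18 in u74, so this count does not decide whether scaling by the authors contributed. A shift of a whole column moves all its ratios 1 way, whereas 907 genes were higher in e398 and lower in u74 and 815 the reverse. This argues against a shift of whole columns as the whole cause, but does not cover the scaling of single libraries. A mixture of unlike libraries in the wild-type average may contribute: across 3256 genes with a wild-type average from 2 to under 8, the ratio of the 3 wild-type libraries of small size factor over the 3 of large size factor correlated at 0.6881 with the ratio of e398 over the mean of u74 and u218, which shares no library with it. Genes of higher wild-type average were not covered. Both ratios set smaller size factors over mostly larger ones, so an effect of size factor at low counts cannot be told apart from such a mixture. Genes are not independent replicates, and the labels give no batch, age or collection date for either set of libraries. A difference by genotype remains open beside it, as untested.

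Oocyte, sperm and yolk genes differed between the mutants. The median log2 ratio of col-19, made in the epidermis, and 6 vitellogenin genes, made in the intestine, was -8.479 in u218 against u74. These genes belong to the adult-onset and yolk genes already seen to be lower, so this value restates the pattern and is no separate test. It shows only that transcripts of these somatic tissues were not alike in u218 and u74. Fewer germ cells together with a somatic difference stay open. A younger age at collection could lower all of these together. Within u218, library 3 exceeded the mean of libraries 1 and 2 for sperm genes by a median log2 ratio of 3.678, so libraries of 1 genotype differed as well. Age and genotype cannot be told apart here, since the labels give no age or time of collection within the L4 stage.

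Genes lower in all 3 mutants came in part from 1 wild-type library. Of 220 such genes examined, 54 (24.5%) resolved to whole reads of wild-type library 3 with at most 10 reads in the other 5, against 0 values moved off their place and 18 of 1000 other genes (1.8%). Males among the animals of that library are a candidate explanation: 4 of 8 male-neuron genes, picked after the data were seen from 20 sex determination and male genes fixed beforehand, had most of their wild-type signal in library 3. These were lov-1 (195 reads, 12 elsewhere), cwp-1 (172 and 6), cwp-2 (80.7% of the signal) and cwp-3 (33 and 2); pkd-2, cwp-4, cwp-5 and klp-6 could not be resolved. Of these, cwp-4 (327 in wild type, 526 in e398), cwp-5 (114 and 211) and klp-6 (81.1 and 146) were higher in e398 than in wild type, and so were not among the genes lower in all 3 mutants. Of the 4 resolved genes, only lov-1 was among them (21.9 in wild type, then 7.00, 2.60 and 1.61). The wild-type averages of cwp-1, cwp-2 and cwp-3 (19.1, 18.5 and 4.09) and their mutant averages were under 20, so these genes were not considered. For cwp-3 the e398 average (4.29) was not lower. For these male-neuron genes up to 15 reads elsewhere were allowed, and at that limit 4 of 220 values moved off their place resolved, against 0 at the limit of 10. Among 219 genes at least 2-fold lower in all 3 with a wild-type average from 2 to under 8, 42 (19.2%) had most of their signal in library 3. For 84 (38.4%) it was library 6. Among 3037 other genes of that level the shares were 4.15% for library 3 and 30.5% for library 6. No biological explanation was tested for the other lower genes.

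Other splits of the same libraries were counted for each limma result. Against wild type, 2 of 84 splits gave as many genes as the real 35 for e398, 4 of 84 as the real 23 for u74 and 2 of 84 as the real 28 for u218. These shares do not decide whether chance can be excluded, because genes entered by their real wild-type average, which favours the real split. The highest other splits called 575, 269 and 153 genes, several times the real counts, and each set 3 wild-type libraries of like size factor apart. That for e398 left its libraries grouped with wild-type libraries 4 to 6, and those for u74 and u218 left theirs with 1 to 3. These splits largely follow size factor. A structure that spans wild-type and mutant libraries may underlie them, or an effect of size factor at low counts. These cannot be told apart here, and for the mutants neither can be told apart from genotype. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real values were 3342, 2729 and 1636 for u74 against e398, u218 against e398 and u218 against u74, with a highest other of 0 in each, and 416 with a highest other of 0 for the wild-type libraries of small against large size factor (1 split as large, the real one, in these 4). With wild-type libraries of like size factor they were 25 for e398 (highest other 4), 6 for u74 (highest other 34; 2 splits as large) and 22 for u218 (highest other 8).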

How the results depend on the processing

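All alternatives for limma were chosen after seeing the data; those for averages were fixed beforehand, except where said. Among counts of genes at 2-fold or more, 35 stayed within 1.5 times the main count and 13 moved, with no filter (e398 8745, u74 10423 and u218 12426 against wild type, 16984 for u74 against e398), at 1.5-fold (9496 for e398, 9703 for u74, 9977 for u218 against u74) or at 4-fold (1742, 3009 and 4060 against wild type, 6746 for u74 and 7121 for u218 against e398, 2763 for u218 against u74). These thresholds admit more or fewer genes by construction. The 261 genes with a shared direction became 773 with no filter, 112 at a minimum of 100 normalized counts, 434 at 1.5-fold and 143 at 4-fold. At pseudocounts 0.5 and 10, after recentring or with TMM factors, 3 ratios of named genes fell short of 2-fold and 629 kept their label. Those that fell short included fbn-1 in u218 and sad-1 in u74. No called ratio changed sign, which pseudocounts or shifts of this size could not bring about. Of 114 medians by list and mutant, 62 lay outside the central 95% of random lists, and 63, 63 and 61 did so at pseudocount 10, after recentring and at a minimum of 100 normalized counts; TMM factors were not run for this count. The ratio of mec-8 in u218 became 1.15 after recentring and 1.198 with TMM factors, the latter added after seeing the data, since both shift all ratios upward. By limma, e398 against wild type gave 409 genes with voom; u74 gave 15 at a minimum mean of 2 and 6 with the wild-type libraries of large size factor alone; u218 gave 56 with voom, 48 at pseudocount 5 and 18 at a minimum mean of 2. The cause was not tested. Leaving out 1 library gave 13 to 79 genes for e398 (15 and 13 without e398 libraries 1 and 3, 22, 21 and 79 without wild-type libraries 1, 2 and 6), 4 to 33 for u74 (7, 5 and 4 without u74 libraries 1, 2 and 3, 13 without wild-type library 5) and 10 to 37 for u218 (14 and 10 without u218 libraries 1 and 2). It gave 2478 to 3856 for u74 against e398, 1285 to 2946 for u218 against e398 (1417 and 1285 without u218 libraries 1 and 2, 1557 and 1725 without e398 libraries 1 and 3) and 512 to 3403 for u218 against u74 (753, 687 and 3403 without u218 libraries 1, 2 and 3, 767, 512 and 601 without u74 libraries 1, 2 and 3). For wild-type libraries of small against large size factor it gave 0 to 410 (0 by limma without library 1, with 418 at unadjusted p under 0.05; 162, 270 and 260 without libraries 2, 3 and 4), and a minimum mean of 2 gave 961. No paired analysis was possible because the deposited columns are averages and the recovered libraries carry no replicate numbers. For that reason a replicate block, each labelled replicate left out, and wild-type replicates 1 to 3 or 4 to 6 alone were not run; count models on recovered reads were not run either.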
